A study of Homo sapiens with 12 samples.

How the data were processed

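Polyadenylated RNA was sequenced from HCT116, a human colorectal carcinoma cell line, in 12 libraries that form 4 groups of 3. Per the labels, cells received 10 nM of either a pool of siRNAs against ELOA or a non-targeting siRNA of another chemistry, the siRNA medium was removed after 6 h, and about 42 h later thapsigargin was added to 300 nM. RNA was taken at 0 h or 4 h of thapsigargin. Libraries were made with a strand-specific kit and read as 50 bp single reads on a HiSeq 2500 instrument, per the labels' protocols. The groups are called non-targeting (NT) 0 h, NT 4 h, ELOA siRNA 0 h and ELOA siRNA 4 h, and were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be partly technical. The labels give 300 nM thapsigargin for all 12 libraries, including those at 0 h, and do not say whether the 0 h cells received vehicle. The 0 h libraries were read as having had no time of exposure.

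The authors deposited TPM (transcripts per 1e6 transcripts) for 60623 Ensembl genes, made with RSEM after alignment with STAR 2.7.3a to build hg38 and base calling with bcl2fastq 2.18, per the submitters' processing notes. The RSEM version, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited TPM carry at most 2 decimals and sum to between 999999.22 and 1000000.6 in each library. TPM keep no depth, so the depth per library is unknown and no counting interval was computed. The precision of a value is given by the spread between the 3 libraries of its group. TPM are also shares of a total, so a change is relative to the rest of the library.

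Gene names came from the deposited table. Of its names, 14 had been turned into dates by a spreadsheet, and all 14 were restored by gene ID from a table of approved symbols. Among the tested genes 18 names were repeats of another ID's name. Positions, gene types and GC content were taken from GENCODE v29 (GRCh38), matched by gene ID for 13482 of 13545 tested genes (99.5%), and GC content was that of the longest transcript of 11697 protein-coding genes.

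Expression was analysed as log2(TPM + 1) for the 13545 genes with a mean of at least 1 TPM over the 12 libraries. All fold changes are on this scale, which understates the change of low genes. One model with the 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance and 8 residual degrees of freedom before moderation. The 5 contrasts were the thapsigargin effect with each siRNA, the ELOA siRNA effect at each time, and the interaction, which is the thapsigargin effect with ELOA siRNA minus that with non-targeting siRNA. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Thapsigargin-induced genes were those with a called effect averaged over both siRNAs and a log2 fold change of at least 1, a choice that is independent of the interaction in this balanced design.

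A set of 22 gene lists was fixed before the data were examined, together with the groups, the tests and the alternatives. The 18 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 18 lists within a contrast, and again with an estimated correlation. The smaller lists are given as single genes. For 4 lists the mean log2(TPM + 1) of the members was taken per library, and the difference in thapsigargin effect was tested by exact permutation of the siRNA labels within each time, over 400 assignments, two-sided. The smallest p these can give is 0.005. An exact permutation of 3 libraries against 3 has 20 assignments and cannot go below p = 0.1.

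The genes named in the text follow a rule set beforehand: in each contrast the 10 largest called changes in each direction among genes with approved-style symbols whose libraries do not overlap between groups (no such condition for the interaction), ELOA, 12 marker genes of endoplasmic reticulum stress, up to 4 members of each list with the largest change, and the 10 lowest and 10 highest interaction terms among induced genes. Small nucleolar RNAs, pseudogenes and readthrough genes reached by that rule are uncertain, because short reads are shared among near-identical copies and a length-scaled unit is unstable for short genes. Most are left out of the text. HSPA1A and HSPA1B are near-identical and may exchange reads.

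The scripts were tested on simulated data drawn from the NT 0 h means and the spreads of the 13545 real genes, with 200 changed genes. Each gene was drawn independently of the others, and no thapsigargin effect was included. The shares and the camera p below therefore hold for genes without correlation between them, not for the real lists. For the ELOA siRNA effect at 0 h, 73.1% of genes changed by a log2 fold of 0.5, 94% of those changed by 1 and 97% of those changed by 2 were recovered, and 4.35% of calls were false. For the interaction the shares were 44.8%, 83.6% and 93.9%, with 3.9% of calls false. When the ATF6 list of the interaction was lowered by 0.3 in the simulated ELOA siRNA 4 h libraries, camera gave an adjusted p of 1.23e-34 while the exact permutation of the list mean gave p = 0.065, so that permutation test had little power against a difference lying at a single time point. It also cannot give a small p where the siRNA changes a list by a similar amount at both times. Exchanging some or all of the labels at 1 time turns that shared change into a larger difference.

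The alternatives were a pseudocount of 0.1 or 0.5, no filter on low values, a filter at a mean of 5 TPM, division of each library by its median-of-ratios factor, TPM rescaled after removal of mitochondrial genome and ribosomal protein genes, the replicate number as a block, a fit of the compared groups alone, and each library left out in turn. A correction for a trend of each library with GC content was added after seeing the data.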

Results

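The data were gene-level TPM values of HCT116 colorectal carcinoma cells in which ELOA, the transcriptionally active subunit of the Elongin elongation factor, was targeted by siRNA, with and without 4 h of 300 nM thapsigargin. Thapsigargin inhibits the calcium pump of the endoplasmic reticulum (ER) and so triggers the unfolded protein response. Each of the 4 groups held 3 libraries, and between 13174 and 13882 genes reached 1 TPM per library. Libraries of a group correlated at Pearson r between 0.991 and 0.993 across genes, and libraries of different groups at 0.954 to 0.989. The first principal component, with 59.7% of the variance, separated the time points and the second, with 15.5%, separated the siRNAs. Genes are not independent replicates, so these correlations describe the libraries only. No library was a copy of another, since at most 82 of the 13545 tested genes had equal values in any pair.

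ELOA itself was lower in every library that received its siRNA. Its level was 36.1 ± 1.02 TPM (SD, n = 3) in NT 0 h and 11.7 ± 0.541 in ELOA siRNA 0 h, so that 32.3% remained. At 4 h the levels were 26.8 ± 0.635 and 8.89 ± 0.474 TPM, with 33.2% remaining. In limma the log2 changes were -1.55 (SE 0.0547, adjusted p = 4.41e-09) and -1.49 (adjusted p = 7.02e-09), and the exact permutation p was 0.1 at each time, the smallest that 3 libraries against 3 can give. Thapsigargin lowered ELOA in both backgrounds, by a log2 change of -0.42 with non-targeting siRNA and -0.36 with ELOA siRNA. ELOA lies on chromosome 1 from 23743155 to 23762059, plus strand (GRCh38). The other tested members of the Elongin and CUL5 ligase list changed little: at 0 h ELOC fell by 0.10 (adjusted p = 0.0117), and ELOB was at 0.08 (adjusted p = 0.152).

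**Figure D1:**
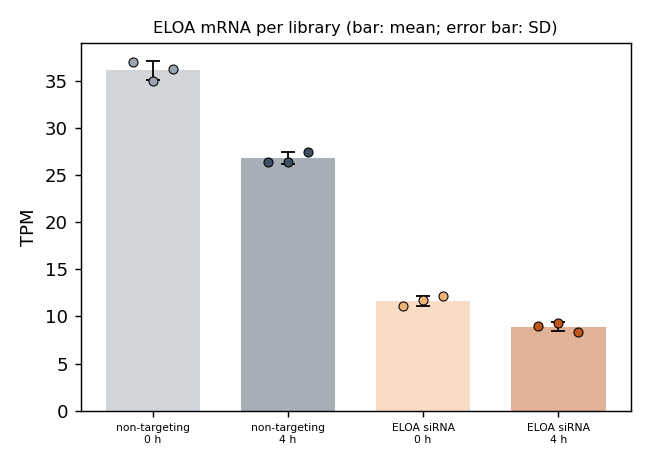
ELOA mRNA in TPM for each of the 12 libraries (dots), with the mean (bars) and SD (error bars) of each group of 3. The ELOA siRNA groups have means of 11.7 and 8.89 TPM against 36.1 and 26.8 TPM with non-targeting siRNA.

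The thapsigargin effect with non-targeting siRNA gives the response of control cells to ER stress. Transcripts of all branches of the unfolded protein response rose. HSPA5, which encodes the ER chaperone BiP (chromosome 9, 125234853 to 125241330, minus strand, GRCh38), went from 284.9 ± 4.33 to 4046 ± 54.7 TPM (SD, n = 3), a 14.2-fold rise. DDIT3, which encodes the stress transcription factor CHOP (chromosome 12, 57516588 to 57521737, minus strand), rose 63.6-fold from 18.4 to 1230.0 TPM, and HERPUD1, a component of ER-associated degradation (chromosome 16, 56932048 to 56944863, plus strand), rose 37.2-fold. The PERK-ATF4 targets CHAC1, DDIT4 and TRIB3 rose by log2 changes of 4.49, 4.48 and 3.63. The chemokine genes CXCL8 and CCL20 rose by 5.02 and 4.47. Among the genes that fell, BMP4 went from 90.5 ± 1.26 to 11.0 ± 0.612 TPM, a log2 change of -2.94, the cytosolic chaperone gene HSPA8 changed by -1.72 and the Wnt feedback gene AXIN2 by -1.95.

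By list, 17 of 17 ATF6 targets rose with a median log2 change of 2.34, among them SEL1L (3.24) and HYOU1 (2.78) (camera adjusted p = 5.07e-19). Of 33 PERK-ATF4-CHOP targets 33 rose (median 1.71, adjusted p = 6.13e-26), and of 23 XBP1 targets 22 rose and 1 was not called (median 0.68, adjusted p = 1.34e-11), led by DNAJB9 (3.82), SEC24D (2.54) and EDEM1 (2.30). Among 21 ERAD components 14 rose and 2 fell (adjusted p = 5.41e-06). This list is not separate from the others: it shares SEL1L, SYVN1 and HERPUD1 with the ATF6 list. It also shares EDEM1, EDEM2, DERL1 and DERL2 with the XBP1 list. Cholesterol synthesis genes rose in 19 of 21 cases, with STARD4 at 3.41 and HMGCS1, an early enzyme of the mevalonate pathway, at 3.01 (adjusted p = 1.11e-12). All 21 immediate early genes rose (median 1.62, adjusted p = 7.41e-16), among them DUSP5 (2.85) and EGR1 (2.68). Of 12 cytosolic heat shock genes 11 fell and 1 rose, with HSPA1B at -2.35 and DNAJA1 at -1.28 (adjusted p = 3.05e-06). Each of these 7 lists kept an adjusted p under 0.05 with an estimated correlation. Adjusted over the list alone, the counts were the same except that 1 XBP1 target was then called lower.

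Other lists moved less. Of 22 cell cycle genes 15 fell and 1 rose, led by CCNE1 (-0.93) and PCNA (-0.74), with a camera adjusted p = 0.00128 and an adjusted p = 0.056 with an estimated correlation. Among 13 transcripts of the mitochondrial genome 12 fell (median -0.35, adjusted p = 6.55e-06, adjusted p = 0.293 with an estimated correlation), and of 81 cytosolic ribosomal protein genes 35 fell and 9 rose (adjusted p = 0.0363, adjusted p = 0.696 with an estimated correlation). Of 88 listed replication-dependent histone genes only 19 were tested, and 10 of these rose (adjusted p = 0.0122, adjusted p = 0.131 with an estimated correlation). Polyadenylated RNA was sequenced, so these and later histone values cannot speak for histone transcripts without a poly(A) tail. The ribosomal call ended under median-of-ratios scaling (adjusted p = 0.0803). The p53 targets were divided, with 8 higher and 9 lower of 22 (adjusted p = 0.507), as were Mediator subunits (9 higher and 6 lower of 32, adjusted p = 0.642) and RNA polymerase II elongation factors (13 higher and 11 lower of 30, adjusted p = 0.642). ELL2, which encodes an elongation factor, rose by 2.32. The glycolysis and hypoxia list (6 higher and 9 lower of 22, adjusted p = 0.42), the interferon list (5 higher and 3 lower of 12, adjusted p = 0.322), the colon epithelium list (4 higher and 3 lower of 9, adjusted p = 0.281) and the Elongin list (1 higher and 4 lower of 7, adjusted p = 0.42) passed no list test. For the Mediator, elongation factor and colon lists the median lay below 0 while the mean and the test pointed up.

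In all, 3570 genes were higher and 3822 lower after thapsigargin in the non-targeting background, 54.6% of those tested. After rescaling without mitochondrial and ribosomal protein genes 3122 were higher and 4589 lower. A log2 change of at least 1 was reached by 533 of the higher and 139 of the lower genes. Protein-coding genes with more GC tended to be lower (Spearman rho -0.202 across 11697 genes).

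The thapsigargin effect with ELOA siRNA gives the response of cells that received the ELOA siRNA. The same families moved: HSPA5 went from 316.9 ± 5.31 to 3930.0 ± 60.5 TPM (12.4-fold, SD, n = 3), DDIT3 rose 48.2-fold, HERPUD1 31.7-fold and CHAC1 22.3-fold. BMP4 fell by 2.11 on the log2 scale, HSPA8 by a change of -2.04 and SMAD7, an inhibitor of TGF-beta signalling, by a change of -1.87. In total 4346 genes were higher and 3517 lower, but 3931 and 4012 with median-of-ratios scaling and 3940 and 4018 after rescaling without mitochondrial and ribosomal protein genes. Of the genes higher in the non-targeting background 3109 were also higher here, against 1145.5 for independent lists. Lower in both were 2824, against 992.4. These contrasts share no library, but they share each gene's estimate of the spread. That can by itself raise the overlap above that of independent lists. Genes called in opposite directions numbered 11 and 35. Fold changes correlated across genes at Pearson r = 0.867.

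All 17 ATF6 targets rose again (median 2.33, adjusted p = 2.85e-16), as did all 33 PERK-ATF4-CHOP targets (median 1.56, adjusted p = 4.39e-22) and 22 of 23 XBP1 targets, with 1 lower (adjusted p = 2.05e-09). ERAD components (14 higher, 4 lower of 21, adjusted p = 0.000111), cholesterol synthesis (18 higher, 1 lower of 21, adjusted p = 1.47e-08) and immediate early genes (21 of 21 higher, adjusted p = 1.75e-13) also rose, and heat shock genes fell (11 of 12, adjusted p = 1.25e-06). Of 22 cell cycle genes 18 fell and 1 rose (adjusted p = 7.02e-07), and of 22 glycolysis and hypoxia genes 15 fell and 5 rose (adjusted p = 0.0129). The glycolysis call ended with a filter at 5 TPM (adjusted p = 0.0601). Ribosomal protein genes fell in 61 of 81 cases and rose in 8 (adjusted p = 2.99e-08, adjusted p = 0.46 with an estimated correlation). Mitochondrial transcripts, which fell in the non-targeting background, had 3 lower and 1 higher of 13 (adjusted p = 0.342). The remaining lists passed no list test here: histones (7 higher and 2 lower of 19, adjusted p = 0.314), p53 targets (8 and 7 of 22, adjusted p = 0.837), the interferon list (3 and 1 of 12, adjusted p = 0.465), Mediator (11 and 5 of 32, adjusted p = 0.444), elongation factors (13 and 10 of 30, adjusted p = 0.696), the Elongin list (1 and 3 of 7, adjusted p = 0.314) and colon epithelium (4 and 2 of 9, adjusted p = 0.5). For p53 targets the median (-0.03) and the test pointed down with a mean just above 0, and for the colon list the median (-0.02) lay below 0 while the mean and the test pointed up.

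**Figure D2:**
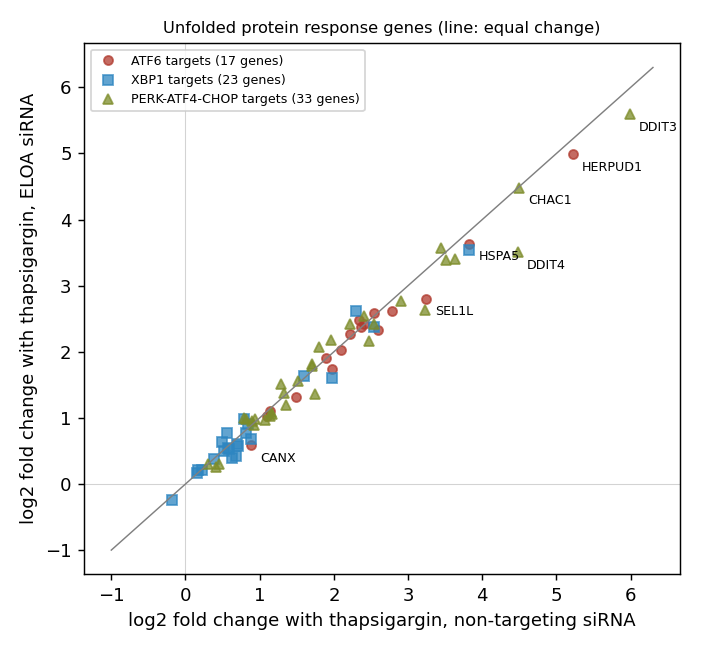
Log2 fold change with thapsigargin in the non-targeting background (x) against that with ELOA siRNA (y) for members of the ATF6 (17 genes), XBP1 (23) and PERK-ATF4-CHOP (33) lists, with the line of equal change. DDIT3 lies at 5.99 and 5.59, DDIT4 at 4.48 and 3.50, and HSPA5 at 3.82 and 3.63, below the line.

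The ELOA siRNA effect at 0 h compares the 2 siRNA reagents with no time of exposure to thapsigargin, although the labels give 300 nM for these libraries too. Targets of p53 rose together: 20 of 22 tested members were higher and 0 lower, with a median log2 change of 0.53. CDKN1A, the cell cycle inhibitor p21, went from 103.5 ± 1.07 to 220.3 ± 4.28 TPM (SD, n = 3), a log2 change of 1.08, and BTG2, TP53I3 and GDF15 rose by 1.25, 1.19 and 1.09. Cell cycle genes fell in 19 of 22 cases (median -0.20), among them RRM2 (-0.45) and AURKA (-0.40), and cholesterol synthesis genes in 16 of 21 (median -0.25), with FDFT1, squalene synthase, at -0.73 and IDI1 at -0.53. Outside the lists, the growth factor gene MDK rose from 101.4 ± 4 to 258.1 ± 6.2 TPM (log2 1.34), and CHCHD3, a component of the mitochondrial inner membrane organising complex, fell from 92.5 ± 2.64 to 33.0 ± 1.12 TPM (log2 -1.46).

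Among ER stress genes, ATF6 targets were slightly higher with ELOA siRNA at 0 h. Of 17 ATF6 targets 13 rose and 1 fell, with a median of 0.15: SEL1L by 0.35, HERPUD1 by 0.33 and HSPA5 by 0.15 (adjusted p = 0.00026), while SYVN1 was at -0.26 and HSP90B1 at -0.04 (adjusted p = 0.23). XBP1 targets rose in 10 of 23 cases (DNAJB9 by 0.38). PERK-ATF4-CHOP targets went both ways, with 13 lower, such as GARS (-0.43) and ASNS (-0.40), and 3 higher, such as DDIT4 (0.67) and SESN2 (0.55), of 33. Heat shock genes fell in 6 of 12 cases and rose in 1 (HSPH1 -0.43). Immediate early genes rose in 11 of 21 and fell in 3 (NR4A2 1.09). Histone genes rose in 9 of 19 tested of 88 listed, such as HIST1H2AC (1.07), at low levels of 2.54 ± 0.32 and 6.4 ± 0.384 TPM. In the interferon list IRF9, IFI6, ISG15 and DDX58 rose, by 0.70, 0.54, 0.50 and 0.49, and 8 of 12 were not called. SYVN1 lost its call without NT 0 h replicates 1 or 3 or ELOA siRNA 0 h replicates 1 or 3 (adjusted p up to 0.126).

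The camera adjusted p was 4.66e-15 for p53 targets, 2.39e-11 for the cell cycle, 1.29e-10 for cholesterol synthesis, 0.00292 for ATF6 targets, and 0.000192 for both heat shock and histone genes, and all 6 kept an adjusted p under 0.05 with an estimated correlation. The calls for XBP1 targets (0.00936, adjusted p = 0.0557 with an estimated correlation), immediate early genes (0.00352, adjusted p = 0.266 with an estimated correlation), the interferon list (0.0409, adjusted p = 0.0909 with an estimated correlation) and PERK-ATF4-CHOP targets (0.0429, adjusted p = 0.145 with an estimated correlation) did not. With a filter at 5 TPM the interferon and PERK-ATF4-CHOP lists each had an adjusted p of 0.0712. No call was made for the Elongin list (0 higher and 2 lower of 7, adjusted p = 0.373), Mediator (2 and 5 of 32, adjusted p = 0.152), elongation factors (5 and 6 of 30, adjusted p = 0.818), ERAD (6 and 2 of 21, adjusted p = 0.625), glycolysis (3 and 4 of 22, adjusted p = 0.515), colon epithelium (3 and 1 of 9, adjusted p = 0.662), ribosomal proteins (29 and 10 of 81, adjusted p = 0.152) or mitochondrial transcripts (3 and 0 of 13, adjusted p = 0.515). Median, mean and test differed in sign for the Elongin, elongation factor, glycolysis and colon lists. The ribosomal list was called higher without a filter (adjusted p = 0.00774). Adjusted over the list alone, 20 p53 targets, 21 cell cycle genes, 17 cholesterol genes and 13 ATF6 targets were called in these directions. Over all genes, 2005 were higher and 1459 lower, and 33 rose and 13 fell by a log2 change of at least 1. With median-of-ratios scaling 1722 were higher and 1764 lower, so the excess of higher genes depends on the scaling. That scaling tends to an even split by construction, so it cannot decide whether the excess is real.

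Few markers of other cell types were measured. Of 10 fibroblast markers COL1A1 and ACTA2 were tested, of 12 blood cell markers CD68 and HBA2, of 6 endothelial markers 0, and of 8 markers of HEK293 or HeLa cells HOXB7 and TBX3. The untested markers had means of at most 0.812 TPM. With ELOA siRNA at 0 h ACTA2 rose from 2.26 ± 0.503 to 6.26 ± 0.432 TPM (log2 1.17) and CD68 from 3.47 ± 1.17 to 10.4 ± 1.7 TPM (log2 1.38), HOXB7 rose from 60.3 ± 0.338 to 68.6 ± 1.14 TPM (log2 0.18), and COL1A1 (0.50, adjusted p = 0.0556), TBX3 (0.25, adjusted p = 0.13) and HBA2 (-0.27, adjusted p = 0.613) were not called. Without NT 0 h replicate 3 COL1A1 was called higher, at 0.60. At 4 h ACTA2 (1.27), COL1A1 (0.77, adjusted p = 0.00419), TBX3 (0.59, adjusted p = 0.00132) and HOXB7 (0.22) were higher with ELOA siRNA, and CD68 (0.44, adjusted p = 0.0899) and HBA2 (-0.17, adjusted p = 0.734) were not called. With thapsigargin COL1A1 rose by 0.70 in the non-targeting background and by 0.97 with ELOA siRNA, HOXB7 changed by -0.50 and -0.47, and CD68 rose by 0.85 in the non-targeting background and was not called with ELOA siRNA (-0.09, adjusted p = 0.714), with an interaction of -0.94 (adjusted p = 0.07).

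The ELOA siRNA effect at 4 h compares the same reagents after exposure. The p53 targets again rose in 18 of 22 cases and fell in 3 (median 0.49), with TP53I3 at 1.46 and PHLDA3 at 1.13. Cholesterol synthesis genes fell in 19 of 21 cases, with FDFT1 at -1.02 and INSIG1 at -0.62, and cell cycle genes in 18 of 22 (CCNE2 -0.66). PERK-ATF4-CHOP targets fell in 19 of 33 cases and rose in 6, with DDIT3 at -0.38 and the amino acid transporter gene SLC7A5 at -0.39. ATF6 targets did not move as a list: 4 rose (SDF2L1 0.33, CRELD2 0.21), 2 fell (CANX -0.23) and 11 were not called, HSPA5 among them (-0.04, adjusted p = 0.139). CHCHD3 (-1.50) and MDK (1.67) changed as at 0 h, the heme oxygenase gene HMOX1 fell by 1.01, and the nuclear receptor gene NR4A2 rose by 1.71. Mitochondrial transcripts were higher in 12 of 13 cases (MT-ND1 0.68), beside a mitochondrial share of TPM of 10.7 ± 0.65% against 8.39 ± 0.0862% (SD, n = 3). The share was 10.7 ± 0.249% in NT 0 h and 11.2 ± 0.0819% in ELOA siRNA 0 h, so NT 4 h stood apart. The fall with thapsigargin, this difference and the interaction of mitochondrial transcripts thus rest largely on the NT 4 h group.

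Camera gave an adjusted p = 8.37e-15 for cholesterol synthesis, 3.98e-14 for the cell cycle, 1.4e-05 for p53 targets, 8.55e-06 for PERK-ATF4-CHOP targets, 0.000684 for heat shock (7 lower and 2 higher of 12) and 0.00944 for glycolysis and hypoxia (11 lower and 4 higher of 22), all kept with an estimated correlation. Ribosomal protein genes (38 lower and 11 higher of 81, 7.64e-06) had an adjusted p = 0.569 with an estimated correlation, and mitochondrial transcripts (1.12e-06) an adjusted p = 0.281 with an estimated correlation. ATF6 targets had an adjusted p = 0.574, with a median and mean just above 0 and a test pointing down, because the median over all genes was 0.07. Its median was -0.07 under median-of-ratios scaling. The other lists were not called: XBP1 (6 higher and 2 lower of 23, adjusted p = 0.576), ERAD (6 and 4 of 21, adjusted p = 0.819), Elongin (0 and 1 of 7, adjusted p = 0.166), Mediator (3 and 3 of 32, adjusted p = 0.51), elongation factors (11 and 7 of 30, adjusted p = 0.622), interferon (5 and 2 of 12, adjusted p = 0.238), immediate early (10 and 4 of 21, adjusted p = 0.469), colon epithelium (3 and 2 of 9, adjusted p = 0.593) and histones (9 and 0 of 19, adjusted p = 0.109). Median, mean and test differed in sign for the ERAD, Elongin, Mediator, elongation factor and colon lists. Interferon and histone lists were called under other settings, with no filter (adjusted p = 0.0462) and median-of-ratios scaling (adjusted p = 0.0255), respectively.

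Over all genes, 3541 were higher and 1818 lower, so 66.1% of calls were higher. With median-of-ratios scaling, which tends to an even split by construction, 2523 were higher and 2738 lower, 48% higher. After rescaling without mitochondrial and ribosomal protein genes 4029 were higher and 1506 lower, 72.8% higher, so the excess depends on the scaling. Genes with more GC were relatively higher, at Spearman rho 0.369 across 11697 protein-coding genes, and the NT 4 h libraries had the lowest correlations with GC content (-0.344, -0.366 and -0.226). The ELOA siRNA effects at the 2 times, which share no library, had 1393 genes higher in both against 524.2 for independent lists. Lower in both were 997 against 195.8, and the effects correlated at Pearson r = 0.548 across genes. The shared estimate of each gene's spread can raise this overlap. A GC trend was also present at both times (rho 0.255 at 0 h and 0.369 at 4 h).

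**Figure D3:**
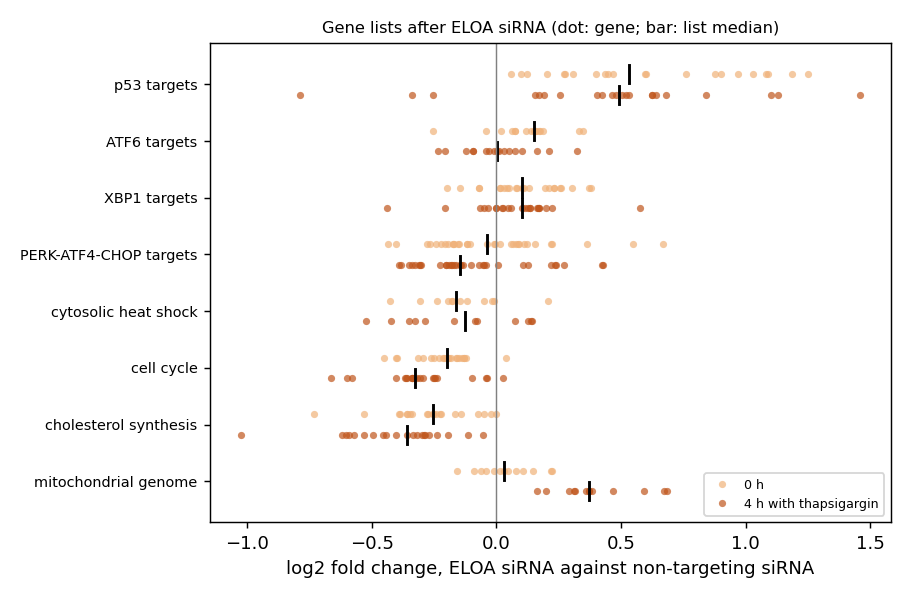
Log2 fold change of ELOA siRNA against non-targeting siRNA for every tested member of 8 gene lists (dots) at 0 h and at 4 h of thapsigargin, with list medians (bars). The p53 medians are 0.53 and 0.49, the cell cycle medians -0.20 and -0.32, the cholesterol medians -0.25 and -0.36, and the ATF6 medians 0.15 and 0.00.

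The interaction asks the question in the study's title, whether the response to ER stress, and to ATF6 in particular, differed between cells with ELOA siRNA and with non-targeting siRNA. Several stress genes rose less with ELOA siRNA. HMOX1 went from 39.9 ± 3.01 to 286.5 ± 22.8 TPM (SD, n = 3) in the non-targeting background and from 44.9 ± 1.75 to 141.5 ± 9.1 TPM with ELOA siRNA, an interaction of -1.18 (adjusted p = 5.9e-05). DDIT4, an inhibitor of mTORC1, had -0.98, and the p53 targets BBC3, GDF15 and CDKN1A had -0.99, -0.62 and -0.55. GDF15 and CDKN1A still ended higher with ELOA siRNA at 4 h, at 191.8 and 274.6 TPM against 138.8 and 189.7 TPM. Their 0 h levels were already higher, at 83.4 and 220.3 TPM against 38.6 and 103.5 TPM. BTG2 (-0.62) was not called with non-targeting siRNA (0.08, adjusted p = 0.323) and fell with ELOA siRNA (-0.54). In the opposite direction, CITED2, a transcriptional coregulator, reached 35.8 ± 4.11 TPM at 4 h with non-targeting and 70.6 ± 3.39 TPM with ELOA siRNA (interaction 0.99, adjusted p = 0.000231), the actin-binding gene CORO6 had 1.55, the calcium channel gene ITPR1 1.06, EGR3 0.99 and NR4A2 0.61.

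Among ATF6 targets 6 of 17 rose less, 0 rose more and 11 were not called, and 8 were lower when adjusted over the list alone. PDIA4 (-0.24, SE 0.039), CANX (-0.30, SE 0.0525) and HSPA5 (-0.20, SE 0.03, adjusted p = 0.00389) were called in each fit that left out 1 library. SEL1L (-0.44, adjusted p = 0.0325) lost its call without NT 0 h replicates 1 or 2, NT 4 h replicates 1 or 2, or ELOA siRNA 4 h replicates 2 or 3, where its adjusted p reached 0.0756, and HERPUD1 (-0.23, adjusted p = 0.0323) kept its call only without NT 0 h replicate 3, ELOA siRNA 0 h replicate 2 or ELOA siRNA 4 h replicate 3. HSP90B1 (0.01, adjusted p = 0.885), XBP1 (0.01, adjusted p = 0.958) and SDF2L1 (0.14, adjusted p = 0.248) were not called. For the list as a whole camera gave an adjusted p = 0.000112 (0.0333 with an estimated correlation), with a median of -0.07.

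The mean level of the 17 ATF6 targets rose by 2.36 log2 units with non-targeting and 2.25 with ELOA siRNA, a difference of -0.11 (SE 0.0171). The exact permutation test gave p = 0.095, or 0.23 after adjustment over 4 lists. The siRNA effect on this list lay almost wholly at 0 h, so reassigning the 4 h labels changed the difference little. That kept this p from being small. With the median over members the difference was -0.05 (exact p = 0.355). With median-of-ratios scaling the difference was -0.16 (exact p = 0.005, the smallest possible). Under that scaling the siRNA effect was 0.0965 at 0 h and -0.0658 at 4 h, of opposite signs. By time, the ELOA siRNA libraries were higher by 0.12 at 0 h (exact p = 0.1) and by 0.01 at 4 h (exact p = 0.2). The differences were -0.07 for PERK-ATF4-CHOP targets (SE 0.0192, exact p = 0.115), -0.04 for XBP1 targets (SE 0.0153, exact p = 0.55) and -0.14 for cholesterol synthesis (SE 0.0181, exact p = 0.575). For all 4 lists the siRNA effect as deposited had the same sign at both times. It was 0.12 and 0.01 for ATF6 targets, -0.02 and -0.09 for PERK-ATF4-CHOP targets, 0.11 and 0.07 for XBP1 targets, and -0.27 and -0.40 for cholesterol synthesis. Assignments that exchange some or all of the labels at 1 time then often give a larger difference than the real one. That keeps this p from being small. The test therefore decides nothing about these lists as deposited.

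**Figure D4:**
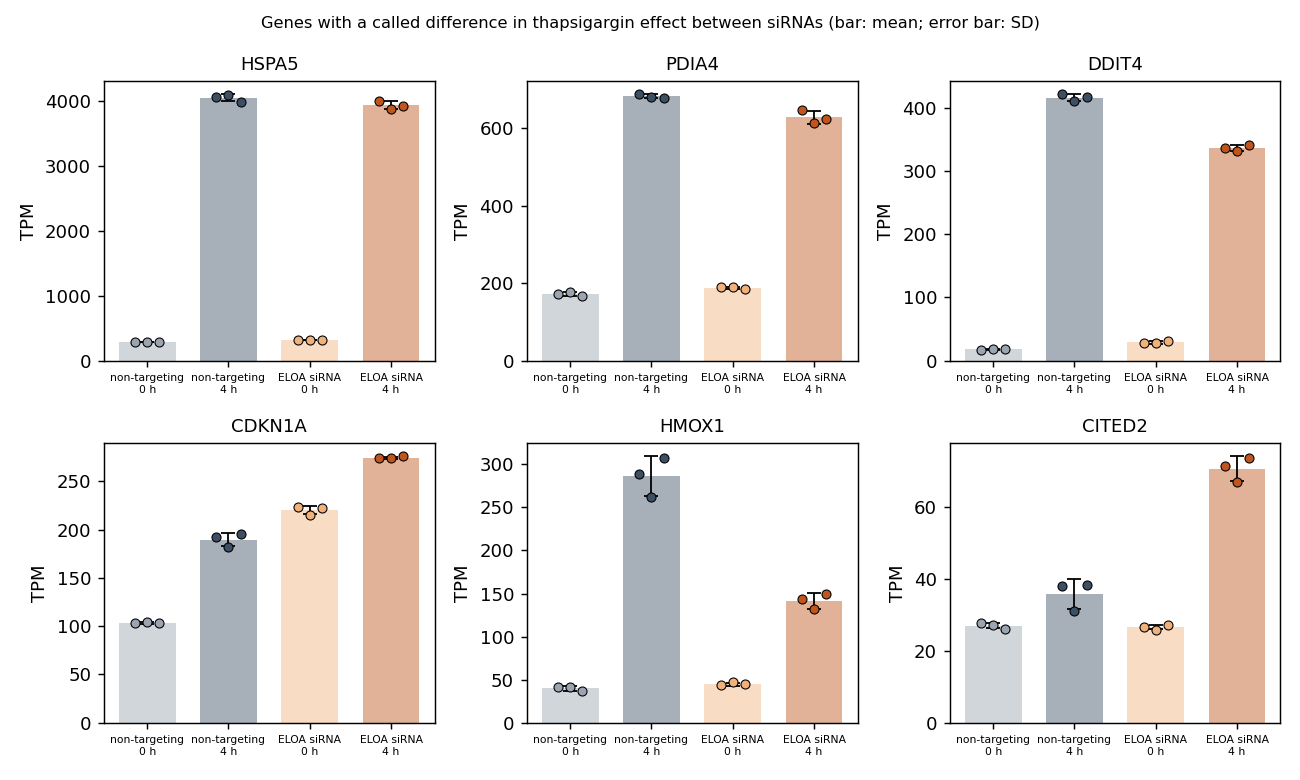
TPM of HSPA5, PDIA4, DDIT4, CDKN1A, HMOX1 and CITED2 in each library (dots), with the mean (bars) and SD (error bars) of each group of 3. HMOX1 reached 286.5 TPM at 4 h with non-targeting and 141.5 TPM with ELOA siRNA, whereas HSPA5 reached 4046 and 3930.0 TPM.

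Other lists also differed in their thapsigargin effect. Cholesterol synthesis (0 higher and 3 lower of 21, adjusted p = 6.49e-06), p53 targets (0 and 6 of 22, adjusted p = 0.000152), the cell cycle (0 and 1 of 22, adjusted p = 4.63e-05) and glycolysis and hypoxia (1 and 6 of 22, adjusted p = 0.0027; PKM -0.24) were lower, and kept this with an estimated correlation. PERK-ATF4-CHOP targets (1 and 7 of 33, adjusted p = 0.00718, SESN2 -0.59, DDIT3 -0.40, TNFRSF10B -0.40) had an adjusted p = 0.0814 with an estimated correlation, and XBP1 targets (0 and 3 of 23, adjusted p = 0.0235, SEC61A1 -0.26) had an adjusted p = 0.0948 with an estimated correlation. Ribosomal protein genes were lower (3 and 25 of 81, adjusted p = 2.99e-12, adjusted p = 0.286 with an estimated correlation), mitochondrial transcripts higher (11 and 0 of 13, adjusted p = 7.45e-11, adjusted p = 0.123 with an estimated correlation) and histones lower (0 and 2 of 19, adjusted p = 0.0459, adjusted p = 0.209 with an estimated correlation). The histone call ended with no filter (adjusted p = 0.149) and with median-of-ratios scaling (adjusted p = 0.142). No call was made for ERAD (0 and 2 of 21, adjusted p = 0.27), Elongin (0 and 0 of 7, adjusted p = 0.595), Mediator (1 and 0 of 32, adjusted p = 0.598), elongation factors (0 and 3 of 30, adjusted p = 0.655), interferon (0 and 0 of 12, adjusted p = 0.548), heat shock (2 and 1 of 12, adjusted p = 0.27), immediate early (4 and 3 of 21, adjusted p = 0.268) or colon epithelium (0 and 2 of 9, adjusted p = 0.134). Median, mean and test differed in sign for the elongation factor, interferon and immediate early lists.

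Of 544 thapsigargin-induced genes, 48 rose less and 34 rose more with ELOA siRNA, and the median interaction was -0.01, with 281 genes below 0. Of the 48 genes, 27 were called higher with ELOA siRNA at 0 h, 30 were called lower at 4 h, and 9 were both. With median-of-ratios scaling 72 rose less and 27 more, and the median was -0.06. Without a filter 47 of these genes were called, and without NT 4 h replicate 1 there were 53.

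Over all genes the interaction was called higher for 386 and lower for 253, a total of 639 of 13545, with 2887 at an unadjusted p under 0.05. With median-of-ratios scaling the split turned to 270 higher and 401 lower, and without a filter 304 genes were called. Protein-coding genes with more GC had higher interaction terms (Spearman rho 0.215 across 11697 genes). With the GC trend removed 343 were called higher and 318 lower, so the excess of higher genes depends on the processing. The total fell to 364 and 366 without ELOA siRNA 0 h replicates 1 and 2, 336 and 328 without ELOA siRNA 4 h replicates 1 and 2, 368 and 407 without NT 0 h replicates 2 and 3, and 339 and 333 without NT 4 h replicates 1 and 2, while it rose to 748 without ELOA siRNA 4 h replicate 3. Of 57 called genes among those the naming rule reached, 19 lost their call in at least 1 of these fits.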

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

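The test of a higher starting level, the tests with the GC trend removed and the breakdown of the reassignments were chosen after the result was seen. The results in this part were picked because the thapsigargin effect differed between the siRNAs in a test of the difference itself.

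Median differences in log2 thapsigargin effect (ELOA siRNA minus non-targeting) were -0.071 for ATF6 targets, -0.034 for XBP1 targets, -0.034 for PERK-ATF4-CHOP targets, -0.12 for cholesterol synthesis, -0.037 for p53 targets, -0.13 for the cell cycle, -0.086 for glycolysis and hypoxia, -0.12 for ribosomal proteins, 0.34 for mitochondrial transcripts and -0.059 for replication-dependent histones. With an estimated correlation 5 of these 10 lists were no longer called: XBP1 targets (adjusted p = 0.0948), PERK-ATF4-CHOP targets (0.0814), ribosomal proteins (0.286), mitochondrial transcripts (0.123) and histones (0.209). Single genes with a strong thapsigargin response that differed were DDIT4 (-0.98), CXCL8 (-0.62), ID2 (-0.61), TSC22D3 (-0.44), SEL1L (-0.44), DDIT3 (-0.40), HSPA8 (-0.33), HERPUD1 (-0.23), TRIB3 (-0.23) and HSPA5 (-0.20), and in the other direction BMP4 (0.83) and ARTN (0.63). BMP4, which fell with thapsigargin, thus fell less with ELOA siRNA. TRIB3 kept its call only without NT 0 h replicate 2 or ELOA siRNA 4 h replicate 3, and HERPUD1 and SEL1L were as unstable as described in the report.

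The smaller rise of the ATF6 list was -0.1133 with a pseudocount of 0.1 and -0.1146 with the GC trend removed, close to -0.1107 as first computed, which argues against compression of low values and against the GC trend as its whole cause. Among 10000 random lists of induced genes the list mean (-0.111) fell at percentile 11.1, inside the central 95%, so a difference of this size may arise among induced genes in general, although the median of the random lists was only -0.0358. The matching on expression was incomplete, with a mean log2 level of 7.83 for the list and 7.24 for the random lists, and 16 of the 17 members were themselves induced genes. The list was already higher by 0.119 (SE 0.0164) at 0 h, which may leave less room for induction, but this stays open: the 4 h difference was 0.01 (SE 0.00484) as deposited and -0.07 (SE 0.0111) under median-of-ratios scaling. A reduced contribution of ELOA to induction remains a hypothesis that these data do not separate from that, and that a second siRNA or rescue of ELOA could test.

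For the number of genes with a called interaction, 8 of 100 drawn assignments of the siRNA labels within time points (200 are possible), the real one included, gave at least the real 639. This does not exclude chance, but the share does not measure chance either. It came only from assignments that keep or exchange the labels of a whole time point. The highest, 6145, came from exchanging the siRNA labels at 1 time point alone, which turns the siRNA effect common to both times into a difference and points to that structure of the samples. Of the others, 0 of the 80 reassignments that mixed the labels at both times reached 639 (highest 2), against 6 of the 18 that kept the labels of 1 time (highest 2443). Mixing labels puts the siRNA effect into the spread within groups, which by itself lowers the calls. The low counts of the mixed reassignments therefore do not measure chance. For the other contrasts 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 with the most calls in each: 7392 against at most 1 for thapsigargin with non-targeting siRNA, 7863 against at most 0 with ELOA siRNA, 3464 against at most 3 for ELOA siRNA at 0 h, and 5359 against at most 0 at 4 h. In these splits too, mixing groups puts their difference into the spread within groups. Low counts then follow from any large difference, so this comparison does not test chance.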

How the results depend on the processing

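The GC correction was chosen after seeing the data, unlike the other alternatives. ELOA stayed lower under each, at 0 h from -1.58 to -1.52 and at 4 h from -1.52 to -1.45 when 1 library was left out. The thapsigargin and ELOA siRNA counts stayed within 1.5 times: leaving out 1 library gave 6727 to 6961 and 7121 to 7483 for thapsigargin, and 2619 to 2870 and 4279 to 4948 for the siRNA. Similar totals do not mean the same genes. Of 5359 genes called for ELOA siRNA at 4 h, 4341 stayed called with median-of-ratios scaling and 3951 with the GC trend removed. At 0 h 3180 and 2763 of 3464 stayed called. The interaction count went to 304 without a filter, which adds many low genes to the adjustment, and from 328 to 748 without 1 library. The median interaction of thapsigargin-induced genes went to -0.0641 under median-of-ratios scaling, from -0.02 to 0.01 without 1 library, and their calls to 47 without a filter and from 53 to 82 without 1 library. The ATF6 difference passed its test under median-of-ratios scaling (-0.16, exact p = 0.005), where the siRNA effects at 0 h and 4 h had opposite signs. It ranged from -0.12 to -0.10 without 1 library (exact p from 0.085 to 0.095). As deposited, the siRNA effect lay almost wholly at 0 h, which keeps this p from being small, so the narrow range of p shows no stability. Median-of-ratios scaling divides each library by 1 factor, so it moves all but low genes by about the same amount. Under it the median interaction over all genes went from 0.035 to -0.012. The shift of induced genes and ATF6 targets under that scaling is therefore not particular to those genes. The causes of the other shifts were not tested further. Of 90 list tests 49 were called, against 33 with an estimated correlation. No called list or named gene reversed, but with the GC trend removed 3934 of the 3951 genes called with and without that correction for ELOA siRNA at 4 h kept their direction, and the XBP1 list lost its interaction call (adjusted p = 0.104) and the ribosomal list its call for thapsigargin with non-targeting siRNA (adjusted p = 0.0907). The replicate number as a block gave 7253, 7740, 3196, 5159 and 501 calls in the 5 contrasts, and ended the list calls of PERK-ATF4-CHOP targets at 0 h (adjusted p = 0.0648) and histones in the interaction (adjusted p = 0.0687). The numbers share no more than a name, since deviations of same-numbered libraries correlated between -0.094 and 0.0361 over 18 pairs and 0 of 12 libraries correlated best with their own number. Depth is unknown, so small changes of low genes cannot be set against counting error.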

Other observations

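The NF-kB and Wnt lists below were chosen after other genes of those pathways had been seen to change, with those genes left out. Among the tests of the remaining patterns, the share of abundant genes, the interferon list, the count of siRNA reagents and the GC correction were chosen after the result was seen.

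Thapsigargin raised inflammatory transcripts. All 10 tested members of a list of 16 NF-kB targets rose in the non-targeting background (median log2 change 1.55), among them CXCL1 (2.61), RELB (2.34), CXCL3 (2.32), NFKB2 (2.11) and TNFAIP3 (1.91), and all 10 rose with ELOA siRNA (median 1.19). Camera, adjusted over the 2 added lists, gave p = 3.82e-08 and 1.87e-06 (0.00153 and 0.00357 with an estimated correlation). NFKBIA, the inhibitor of NF-kB, rose by 0.81 and by 0.36, an interaction of -0.45 (adjusted p = 0.00426), but it was the 1 member of 10 with a called interaction, and NFKB1 was at 0.37 (adjusted p = 0.117). For the list the interaction had an adjusted p = 0.0417, and adjusted p = 0.126 with an estimated correlation. The hypothesis that NF-kB targets beyond those seen before rise with thapsigargin passed its test at 1.55.

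For Wnt targets the same hypothesis was not decided. Of 7 tested members of a list of 15, ZNRF3 (-0.53), CCND1 (-0.38), NOTUM (-0.28) and EPHB2 (-0.28) fell and ETS2 rose (0.66), with a median of -0.281 (adjusted p = 0.136, 0.163 with an estimated correlation). AXIN2, the gene that prompted the list, fell by 1.95.

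Targets of p53 were higher with ELOA siRNA. With the GC trend removed their median at 0 h was 0.557 (0.527 to 0.575 without 1 library, adjusted p = 0.000848 with an estimated correlation), which argues against that trend as the cause. An interferon-type response to the siRNA stays open, since the interferon list had a median of 0.354 but an adjusted p = 0.0909 with an estimated correlation. The reagent and the loss of ELOA cannot be told apart, because 1 ELOA siRNA reagent and 1 control of another chemistry were used. Activation of p53 after loss of ELOA is therefore one candidate explanation, which a second siRNA or rescue could test.

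More genes were higher than lower with ELOA siRNA at 4 h. With the GC trend removed 63.3% of calls were still higher (61.2 to 63.3% without 1 library). That correction keeps the median of each library, so it could not remove a shift common to all genes. The median change over all genes was 0.069 with it and 0.074 without. It therefore cannot decide whether the trend is the cause of the excess. The 100 most abundant genes held 0.442 percentage points more of the TPM total in ELOA siRNA 4 h than in NT 4 h (34.1 ± 0.147% against 33.7 ± 0.151%, SD, n = 3). This argues against a net loss of share by that set only, since a sum can hide opposite changes. The mitochondrial share was higher in ELOA siRNA 4 h than in NT 4 h (10.7 ± 0.65% against 8.39 ± 0.0862%). The ribosomal protein share was lower (17.5 ± 0.537% against 18.5 ± 0.1%). A loss of share by part of the abundant genes therefore stays open. The excess depends on the scaling: 48% of calls were higher with median-of-ratios scaling and 72.8% after rescaling without mitochondrial and ribosomal protein genes. The first of these tends to an even split by construction, so it does not decide whether the excess is real. Its cause stays open, and an effect on total RNA cannot be seen in TPM.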
